A study of Mus musculus with 4 samples.

How the data were processed

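Expression was measured on Affymetrix arrays in 4 samples of laser-captured Purkinje cells from 2 male C57BL/6J mice aged 8 weeks. Per the labels' protocols, frozen brains were sectioned and fixed in an ethanol and acetic acid mixture, cells were cut by laser capture, and RNA was amplified and biotin-labelled by Affymetrix protocols from an input of about a nanogram. How the cells were recognized is not given in the sources used here. The deposited values are intensity signals on a linear scale, 1 per probe set and array, made with GCOS per the submitters' processing notes. The GCOS version, the signal algorithm, its scaling target and the detection calls are not given in the sources used here, and no detection calls were used. Scanner files and dates were not used here, so scan batches could not be tested. From the values, the table holds 45101 probe sets, 1 value was listed as 0, and columns of other samples numbered 0.

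Probe sets were named from the platform annotation table given with the data: 34945 had 1 gene symbol, 932 had several and 9160 had none there, which leaves them unnamed here, and 64 were Affymetrix controls. Probe sets with several symbols or none stayed in the tests without a gene name. Symbols were checked through gene identifiers in a RefSeq table of the assembly GRCm38.p6, used for names only, and 0 needed an update. No genome was given and the values name no build, so no coordinates are printed. The named probe sets covered 18193 genes. Some genes of the lists below were not matched to a probe set with 1 symbol and were not analysed here: the Purkinje cell list kept 18 of 23 genes, the ribosomal list 24 of 37 and the background list 74 of 82.

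The tests of the comparisons, lists, bound, normalization rule and alternatives were chosen before the data were examined, except the leave-one-out values of the spread. Several tests of technical explanations were chosen after. Signals below 0.1 were set to 0.1, log2 was taken, and control probe sets were left out. The rule kept deposited values if the arrays' means, with 2% trimmed from each end, agreed within 5%, and otherwise applied quantile normalization in limma. The trimmed means differed by 46.6% of their average, so quantile normalization was used. A gene's level was that of its probe set with the highest mean. Samples were averaged within each animal, and means and SDs were taken over 2 animals. The background bound of an array was the 95th percentile of genes specific to organs other than brain, and a gene counted as above it when it passed on all 4 arrays. The 21 other lists were compared with all other genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Spread was the median absolute log2 difference of each of 6 pairs of samples.

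Animal 2 was set against animal 1 with lmFit and eBayes with a mean-variance trend in limma 3.58.1 (R 4.3.3), over 14442 probe sets above the bound on at least 2 arrays, with 2 residual degrees of freedom and a false discovery rate of 0.05. Lists of at least 3 genes were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, over 19 lists. Because both animals were untreated and carry the same labels, this comparison describes these samples. Matched random lists, 10000 per list, drew each gene from the 200 nearest in mean signal.

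The genes named were the 15 with the highest mean signal, the 4 highest and 2 lowest of each list (all of a list of 5 or fewer), and, between animals, the 10 called genes with the largest difference in each direction, or all called genes and the 3 with the smallest p in each direction where fewer were called. Other genes of a list were named after their values were seen, where a count of 5 or fewer, an exception or a result adjusted over the list alone called for it.

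The steps were tested on simulated data, with 200 of 14442 probe sets changed between the animals, noise taken from the smoothed spread of the samples, and the granule cell list lowered by 1 on the log2 scale. This simulation was written after the steps had first been run on the real values, where the granule cell list was already lower in animal 2. Of 100 changes of 2-fold, 41% were called, and of 100 changes of 4-fold, 87%, with 3.68% of calls false and all of the recovered changes in the right direction. The simulated granule list had a median of -0.93, and 0 other lists were called. The simulated noise was independent between probe sets and equal in both animals. These rates and the list result hold for such noise only, and unequal or correlated spread was not simulated. With the Purkinje list set above background in a simulated detection, 2 lists were called, that list and the calcium list, which shares genes with it. With no animal effect, the difference between animals less that within was 0.01. The alternatives tried were other bounds, other normalizations, an offset of 16, other filters, other choices of probe sets, a fit without trend, a block for the sample number, and each sample left out.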

Results

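Purkinje cells, the GABAergic output neurons of the cerebellar cortex, were cut by laser from frozen cerebellar sections of male C57BL/6J mice aged 8 weeks, and their amplified RNA was hybridized to Affymetrix expression arrays. There were 4 samples in 1 group, 2 from each of 2 animals, named here by animal and sample as 1-1, 1-2, 2-1 and 2-2. The labels do not say whether samples of 1 animal were separate captures. The tests of probe sets between the 2 animals measure only the spread between these samples. Fisher's exact tests of lists take genes as their units and measure no spread between samples or animals. The granule cell layer, which the series also names, was not analysed here. The comparisons were of genes against a background bound, of samples within and between animals, and of animal 2 against animal 1. The median deposited signal of the arrays was 8.40, 8.50, 9.60 and 11.4 in that order of samples, and their trimmed mean signals were 55.8, 56.8, 72.5 and 87.6. The number of arrays limits the precision of every value. Levels are quantile-normalized log2 signals given as mean ± SD over 2 animals. Probe sets differ in their response to the same amount of RNA, so levels of different genes are not compared.

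The first question was which genes gave a signal above background in the captured cells. Calb1, the calcium-binding protein calbindin, was at 13.68 on all 4 arrays (probe set 1417504_at). It held the top rank each time, so that quantile normalization set its SD to 0. Pcp4, a calmodulin-binding regulator, was at 13.58 ± 0.06 (SD, n = 2 animals), Car8, a carbonic anhydrase-related protein, at 13.50 ± 0.04, and Gng13, a G protein gamma subunit, at 13.38 ± 0.15. The other genes named for their bright signal were the respiratory chain and carrier genes Uqcrb (13.57 ± 0.09), Cycs (13.30 ± 0.15) and Cox7a2 (13.21 ± 0.06). To these were added the malate dehydrogenase gene Mdh1 (13.22 ± 0.01) and the chaperone gene Hspa8 (13.49 ± 0.02). Stmn3, Hint1, Pebp1, Atp6ap2 and Itm2b, with levels from 13.21 to 13.61 and SDs of at most 0.03, and Washc2 (13.24 ± 0.05) completed these 15 genes. All lay near the top rank, where quantile normalization gives nearly the same values on each array, so their small SDs mostly reflect rank. Deposited signals of Stmn3, for example, ran from 10489 in sample 1-1 to 15535 in sample 2-2.

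Of 18193 named genes, 6502 (35.7%) lay above the background bound on all 4 arrays, 3342 on 1 to 3 arrays and 8349 on none. The bound was the 95th percentile of 74 genes specific to organs other than brain, and 3 of these 74 genes, Lor, Tff1 and Tshb, passed it on all 4 arrays. Between 7757 genes (sample 2-1) and 8658 genes (sample 1-2) lay above the bound of a single array. With the bound at the 99th percentile the count on all 4 arrays was 4193 genes. Of the 6502 genes, 4595 had several probe sets, and 2866 of these had at least 1 probe set below the bound on all 4 arrays, so the count belongs to the brightest probe set of each gene. Some levels given below and above came from probe sets that can bind several transcripts, and they were lower on the brightest of the other probe sets. Among those that moved by over 1 were Cnp (7.03), Atxn10 (7.25), Rps20 (4.49), Rps18 (9.37), Gja1 (9.92), Elovl5 (9.09), Vldlr (9.39) and Cox8a (6.63). Of the 15 brightest genes, Hspa8 (9.89), Stmn3 (10.94), Atp6ap2 (10.58), Mdh1 (10.96) and Pebp1 (11.82) did so too.

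All 18 measured genes of the Purkinje cell marker list lay above the bound on all 4 arrays (adjusted p = 6.24e-08, Fisher's exact test against all other genes). Besides Calb1, Pcp4, Car8 and Gng13, the list held Pcp2, a regulator of G protein signalling in these neurons, at 12.94 ± 0.41 (SD, n = 2 animals). It also held Homer3, a postsynaptic scaffold, at 9.29 ± 0.22 and the transcription factor Foxp2 at 8.84 ± 0.02. Genes of metabotropic glutamate receptor signalling and long-term depression passed in 22 of 23 cases (adjusted p = 2.30e-08). Among them were the diacylglycerol kinase Dgkz (13.06 ± 0.23), the phosphatase inhibitor Ppp1r17 (12.92 ± 0.19), the phospholipase Plcb4 (11.95 ± 0.24) and Rgs8 (11.51 ± 0.40). The exception was the phospholipase Pla2g4a, at -0.17 ± 0.58 and below the bound on every array.

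Voltage-gated channel genes lay above the bound in 20 of 23 cases (adjusted p = 2.43e-06, Fisher's exact test). The calcium channel subunit gene Cacna2d2 was at 11.39 ± 0.24, the sodium channel genes Scn2b and Scn1a at 10.79 ± 0.06 and 10.65 ± 0.03, and the potassium channel subunit Kcnab1 at 10.77 ± 0.06. Kcnc2 was below the bound on all 4 arrays, and Kcnc4 passed it on 2. Calcium buffers, pumps and stores passed in 13 of 18 cases (adjusted p = 0.00640), including Pvalb, parvalbumin, at 13.00 ± 0.15 and the endoplasmic reticulum pump Atp2a2 at 13.12 ± 0.09. The pump Atp2b4 and the exchanger Slc8a2 were below the bound on every array. Zebrin-linked genes, which mark stripes of Purkinje cells, passed in 6 of 7 cases (adjusted p = 0.0265), including Aldoc, the zebrin II antigen itself, at 13.13 ± 0.03. The glutamate transporter Slc1a6 was at 9.89 ± 0.03, and Ebf2, known from zebrin-negative stripes, was at 7.11 ± 0.23. Hereditary ataxia genes passed in 14 of 23 cases (adjusted p = 0.0368). Among them were Atxn10 (11.98 ± 0.19), the fatty acid elongase Elovl5 (11.24 ± 0.02) and the reelin receptor Vldlr (10.93 ± 0.04). The ataxia call was lost without sample 2-1 (adjusted p = 0.0613), with the median over probe sets (adjusted p = 0.458) and without probe sets that can bind several transcripts (adjusted p = 0.141). The zebrin call was lost with the median over probe sets (adjusted p = 0.0517).

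Genes of the mitochondrial respiratory chain were above the bound in 30 of 30 cases (adjusted p = 7.90e-13, Fisher's exact test), including Cox8a at 7.75 ± 0.61 and Sdhc at 7.27 ± 0.70 (SD, n = 2 animals). Cytosolic ribosomal protein genes passed in 22 of 24 cases (adjusted p = 9.08e-08), with Rps14 at 11.91 ± 0.18, Rps20 at 11.86 ± 0.02 and Rps18 at 11.82 ± 0.09. The exceptions were Rps16, below the bound on every array, and Rpl14, above it on 1 array, each with 1 probe set.

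Markers of other cells of the cerebellum were measured in the same samples. Bergmann glia and astrocyte genes passed the bound in 15 of 18 cases (adjusted p = 1.66e-04, Fisher's exact test). The gap junction gene Gja1 was at 11.72 ± 0.40, Hopx at 11.58 ± 0.04, Timp4 at 11.08 ± 0.42 and the glial glutamate transporter Slc1a3 at 10.37 ± 0.12 (SD, n = 2 animals). Hes5 and the GABA transporter Slc6a11 were below the bound on all 4 arrays. Granule cell genes passed in 11 of 21 cases (adjusted p = 0.188). Among them were the transcription factor Zic1 at 10.52 ± 0.91, the GABA receptor subunit Gabra6 at 9.30 ± 0.87 and Cbln1 at 8.55 ± 0.71. Slc17a7, a vesicular glutamate transporter gene, and Pax6 were below the bound on every array. Without sample 2-1 the granule list was called above other genes (66.7%, adjusted p = 0.0278), as it was with the median over probe sets (57.1%, adjusted p = 0.0214) and with the bound passed on at least 2 arrays (81.0%, adjusted p = 0.00778).

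Markers of oligodendrocytes passed in 3 of 15 cases (adjusted p = 0.358, Fisher's exact test). The myelin genes Cnp and Mbp were at 11.38 ± 0.48 and 10.18 ± 0.09, and Mog was below the bound on every array. Interneuron genes passed in 2 of 13 cases (adjusted p = 0.233), Lgi2 (7.72 ± 0.57) and Prkcd (6.87 ± 0.47), and the glycine transporter Slc6a5 was below the bound on every array. Blood vessel genes passed in 2 of 16 cases (adjusted p = 0.117), the glucose transporter Slc2a1 (8.67 ± 0.47) and Rgs5 (6.55 ± 0.14). Clic6 alone passed among 12 choroid plexus and meninges genes (adjusted p = 0.117), and none of 4 red blood cell genes did (adjusted p = 0.358). Csf1r alone passed among 14 microglia genes (adjusted p = 0.0527). The microglia list was called below other genes without sample 1-1 (adjusted p = 0.0494), 2-1 (adjusted p = 0.0278) or 2-2 (adjusted p = 0.04996) and, at 0%, with the median over probe sets (adjusted p = 0.0387).

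GABA and glutamate receptor subunits passed in 12 of 26 cases (adjusted p = 0.358, Fisher's exact test). Gabbr1 was at 11.63 ± 0.05, the AMPA receptor subunit Gria2 at 11.02 ± 0.01 and Gabrb2 at 10.83 ± 0.14, and Grin2a and Gabra5 were below the bound on every array. Nuclear hormone receptors passed in 11 of 31 cases (adjusted p = 1). Rora, the receptor gene mutated in the staggerer mouse, was at 11.86 ± 0.09, Nr1d2 at 9.71 ± 0.20 and the progesterone receptor gene Pgr at 9.43 ± 0.15. Among 12 genes of steroid synthesis 2 passed (adjusted p = 0.326), the ferredoxin gene Fdx1 (9.74 ± 0.07) and Hsd11b1 (7.72 ± 0.52), and Cyp17a1 was below the bound on every array. Immediate early and stress genes passed in 7 of 18 cases (adjusted p = 0.848). Fos was at 8.84 ± 0.49 and the chaperone genes Dnajb1 and Hspa1b at 10.94 ± 0.22 and 7.57 ± 1.19, while Arc and Fosb were below the bound on every array. The Y-linked genes Eif2s3y (7.88 ± 0.25) and Kdm5d (6.00 ± 0.69) lay above the bound on all 4 arrays and Uty on 2, while Xist lay below it on all 4, in samples labelled male. This list of 4 genes had an adjusted p of 0.686.

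**Figure D1:**
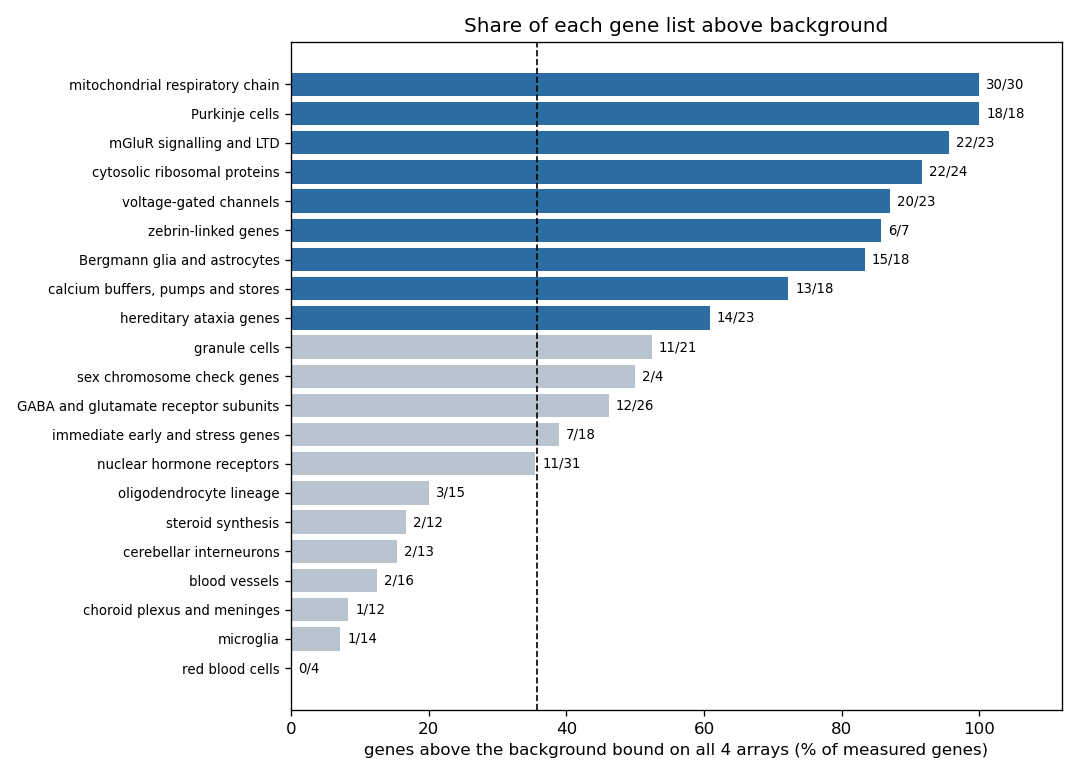
Share of measured genes of each list that lay above the background bound on all 4 arrays (horizontal axis, % of measured genes), with the number of genes beside each bar; dark bars are lists called above other genes by Fisher's exact test, and the dashed line is the share of all genes, 35.7%. The Purkinje cell and respiratory chain lists reach 100%, the glia list 83.3% and the microglia list 7.14%.

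In all, 9 of 21 lists were called above other genes and 0 below by Fisher's exact test with Benjamini-Hochberg adjustment over the 21 lists. At an unadjusted p under 0.05 the microglia list (p = 0.0251, exact) also lay below. Such a test compares list genes with all other genes of the array, many of which are not used in the brain, and its result rests on 1 probe set per gene.

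The second comparison asked how far samples of 1 animal differed from samples of different animals. Over 10101 probe sets above the bound on all 4 arrays, samples 1-1 and 1-2 differed by a median absolute log2 difference of 0.25, and samples 2-1 and 2-2 by 0.42. The 4 pairs from different animals differed by 0.45 to 0.46. The mean over pairs was 0.34 within and 0.46 between animals, a difference of 0.12. Of the 3 ways to split 4 samples into pairs, the real split gave the largest difference, and the other splits gave -0.06 and -0.06. The smallest share that 3 splits allow is 0.333, so this design cannot reach a p under 0.05. The difference rested largely on the animal 1 pair: without sample 1-1 or 1-2 it was 0.035 and 0.040, and without 2-1 or 2-2 it was 0.20 and 0.20. It was 0.26 on values as deposited. The consensus correlation of samples of 1 animal was 0.161. Pearson's r was 0.963 for the animal 1 pair and 0.901 for the animal 2 pair, against 0.901 to 0.905 for pairs from different animals. By that measure the samples of animal 2 were no more alike than samples of different animals.

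**Figure D2:**
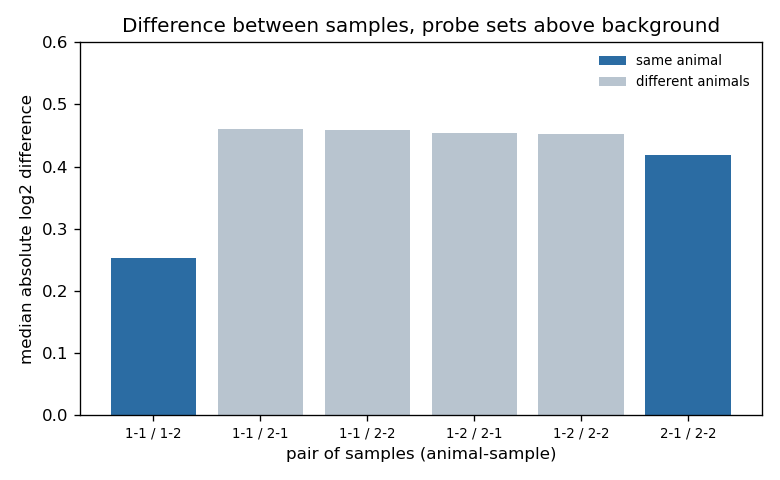
Median absolute log2 difference of each pair of samples (vertical axis) over 10101 probe sets above the background bound; dark bars are pairs from 1 animal, light bars pairs from different animals. The animal 1 pair stands at 0.25 and the animal 2 pair at 0.42, beside 0.45 to 0.46 for the others.

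The third comparison set animal 2 against animal 1, gene by gene. Malat1, a nuclear long noncoding RNA, was higher in animal 2 by 4.01 ± 0.25 on the log2 scale (SE, limma, n = 2 samples per animal, adjusted p = 0.0106) on 1 probe set (1418189_s_at) and by 1.25 ± 0.09 on another (1438403_s_at, adjusted p = 0.0106). Of its other probe sets, not called, 1418188_a_at and 1452378_at stood at 2.15 ± 0.36 and 2.14 ± 0.67, and 1429060_at and 1436202_at at -0.04 ± 0.30 and -0.80 ± 0.27. The plasma membrane calcium pump Atp2b2 was higher by 3.0 ± 0.33 and 0.97 ± 0.11 on separate probe sets, and the sodium pump subunit Atp1b1 by 1.96 ± 0.13 and 0.96 ± 0.10. Other probe sets of these genes were not called: 1420403_at of Atp2b2 stood at -0.35 ± 0.39, and 1423890_x_at and 1451152_a_at of Atp1b1 at 0.13 ± 0.07 and 0.06 ± 0.06. The remaining genes named by size were Rgs7bp (3.78 ± 0.40), Ankrd6 (3.75 ± 0.42), Arhgap5 (2.21 ± 0.17), the semaphorin gene Sema7a (1.65 ± 0.17), the acyltransferase gene Lpgat1 (1.48 ± 0.11), the thrombin receptor gene F2r (1.35 ± 0.15) and the methyltransferase gene Icmt (1.30 ± 0.14). Other probe sets of these genes, where there were any, were not called. They stood at -0.26 ± 0.20 and -0.26 ± 0.25 for Rgs7bp, at 2.14 ± 0.86 for Ankrd6 and at 1.84 ± 0.30 for F2r. For Arhgap5 they stood at -0.01 ± 0.15, 0.39 ± 0.14 and 0.38 ± 0.52, and for Lpgat1 at 0.45 ± 0.14, 0.11 ± 0.33 and 0.10 ± 0.21. Lower in animal 2 were the splicing factor gene Srsf3 (-2.48 ± 0.28), the imprinted gene Ndn (-0.90 ± 0.10), the histone variant gene H2az1 (-0.71 ± 0.06) and Calb1 on the probe set 1448738_at (-0.88 ± 0.10). Other probe sets, not called, stood at -1.48 ± 0.24, -0.96 ± 0.30, -0.74 ± 0.45 and -0.17 ± 0.50 for Srsf3, at -0.72 to -0.42 on 4 probe sets of Ndn, and at -0.46 ± 0.10 for H2az1. Calb1 did not differ on 1417504_at, where normalization fixed its value, and stood at 0.18 ± 0.09 on 1456934_at and at -0.95 ± 0.72 on 1458836_at, neither called. On values as deposited Srsf3 stayed called (-1.96 ± 0.33, adjusted p = 0.0422), and the other lower calls were lost. Ndn then stood at -0.49 ± 0.13 (adjusted p = 0.0952), Calb1 at -0.47 ± 0.13 (adjusted p = 0.0952) and H2az1 at -0.31 ± 0.12 (adjusted p = 0.178). Most probe sets were higher in animal 2 on that scale, which brought these differences closer to 0, and their SEs were larger.

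In total, 20 of 14442 probe sets were called (14 higher and 6 lower in animal 2, limma with Benjamini-Hochberg adjustment), 18 of them with 1 gene symbol, for 11 genes higher and 4 lower. At an unadjusted p under 0.05 there were 2193 probe sets. Genes with the smallest p among those not called were Pcp2 (0.57 ± 0.07, adjusted p = 0.0534), Kitl (3.21 ± 0.39, adjusted p = 0.0551) and Nedd4 (3.07 ± 0.38, adjusted p = 0.0564) with positive differences. With negative ones they were Rnpc3 (-2.67 ± 0.32, adjusted p = 0.0531) and the fatty acid oxidation genes Hadh (-1.35 ± 0.17) and Hadhb (-1.44 ± 0.18, adjusted p = 0.0564 for both). The values of Kitl and Nedd4 came from 1448117_at and 1421955_a_at. On their brightest probe sets, Kitl stood at 0.32 ± 0.08 (1415855_at) and Nedd4 at -0.15 ± 0.38 (1451109_a_at). The count of calls changed strongly when a single sample was left out. The residual spread then came only from the pair of the other animal, and these pairs differed (0.25 in animal 1, 0.42 in animal 2). The change can therefore not be laid to single samples. The count was 0 without the mean-variance trend and 5 with no filter on dim probe sets. On values as deposited, where the median of all probe sets tested was 0.47 higher in animal 2, 243 probe sets were called, 241 of them higher and 2 lower. The hybridization controls, added to the labelled sample just before hybridization, were also brighter in animal 2, by a median ratio of 1.93 over 9 probe sets. Of the poly-A controls, added to the RNA, dap and thr had ratios from 1.48 to 4.10, and phe and lys from 0.738 to 1.02.

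Gene lists were then compared between the animals. Granule cell genes fell in animal 2: 16 of 17 tested genes were lower, with a median log2 difference of -1.0 (adjusted p = 0.00157, camera in limma; adjusted p = 0.471 with an estimated correlation). Neurod1, a transcription factor of granule neurons, stood at -1.97 ± 0.34 (SE, n = 2 samples per animal), Zic1 at -1.29 ± 0.18, Gabra6 at -1.23 ± 0.28 and Cbln1 at -1.0 ± 0.38, and Kcnd2, the 1 gene with a positive value, at 0.67 ± 0.23. Over all probe sets tested 0 of these genes were called, and adjusted over the list alone 3 were, Neurod1, Zic1 and Gabra6, all lower. On values as deposited 12 of the 17 genes were lower, with a median of -0.47 (adjusted p = 1.41e-04), and 16 lay below the median shift of 0.47. In 10 of the 17 genes both samples of animal 2 lay below both of animal 1, as they did in 25.1% of other genes (p = 0.00323, Fisher's exact test). They also did so in 8 of 16 tested genes of Bergmann glia and astrocytes (p = 0.0377 against other genes, and p = 0.732 between these lists, Fisher's exact test).

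None of the other 18 lists tested was called. Purkinje cell markers had a median of 0.07 (18 genes, adjusted p = 0.195). Adjusted over the list alone, 6 of them passed. These were Pcp2, Rgs8 (0.56 ± 0.09), Ppp1r17 (0.27 ± 0.06), Pvalb (0.21 ± 0.05) and Plcb4 (0.34 ± 0.09) above 0 and Gng13 below it (-0.21 ± 0.05, but 0.24 on values as deposited, where none of the 18 genes lay below 0). On the brightest probe set of each gene, 0 of the 18 were called over all probe sets. Calb1 was called lower on 1448738_at (-0.88 ± 0.10), which is not its brightest. Bergmann glia and astrocyte genes had a median of -0.13 (16 genes, adjusted p = 0.442; 0.36 on values as deposited). Gja1 (-0.57 ± 0.09) and Timp4 (-0.60 ± 0.12) passed when adjusted over the list alone, and 0 genes over all. Medians of other cell type lists were -1.03 for interneurons (8 genes, adjusted p = 0.224), -1.26 for blood vessels (6 genes, adjusted p = 0.142), -0.83 for oligodendrocytes (6 genes, adjusted p = 0.169) and -1.46 for microglia (3 genes, adjusted p = 0.365). Adjusted over the list alone, 1 interneuron gene was higher, and 1 oligodendrocyte gene and 2 microglia genes were lower, against 0 over all in each list.

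GABA and glutamate receptor subunits had a median of -0.61 (15 genes, adjusted p = 0.0672). In this list 0 genes passed over all or adjusted over the list alone. Metabotropic receptor signalling genes had a median of 0.17 (22 genes, adjusted p = 0.299), and 6 higher and 1 lower passed when adjusted over the list alone against 0 over all. The calcium list had a median of 0.08 (15 genes, adjusted p = 0.618), with 4 higher and 1 lower when adjusted over the list alone and 1, Atp2b2, over all. These counts use the brightest probe set of each gene. Calb1, also on this list, was called lower on 1448738_at only. For voltage-gated channels the median was -0.01 and the mean 0.18 (22 genes, adjusted p = 0.195), with 2 higher when adjusted over the list alone and 0 over all. Respiratory chain genes (median 0.00, 30 genes, adjusted p = 0.224) had 2 higher and 2 lower when adjusted over the list alone, against 0 over all. Zebrin-linked genes (median 0.04, 7 genes, adjusted p = 0.356) had 1 higher, and immediate early and stress genes (median -0.35, 9 genes, adjusted p = 0.142) 1 lower, against 0 over all in each. Ribosomal protein genes (median 0.11, adjusted p = 0.299), ataxia genes (0.03, adjusted p = 0.407), nuclear receptors (-0.17, adjusted p = 0.932), steroid synthesis genes (-0.73, adjusted p = 0.285) and sex chromosome genes (-0.93, adjusted p = 0.142) had 0 on either count. On values as deposited, where the median over all probe sets was 0.47, 8 lists were called. Besides granule cells, the lower ones were receptor subunits (median -0.06, adjusted p = 0.0193), oligodendrocytes (-0.35, adjusted p = 0.0193), blood vessels (-0.76, adjusted p = 0.0339) and interneurons (-0.51, adjusted p = 0.0478). Immediate early and stress genes were called lower with a median of 0.15 (adjusted p = 0.0340), below that shift. Purkinje cell genes (0.53) and respiratory chain genes (0.44) were called higher (adjusted p = 0.0478 for each). The respiratory chain median also lay below the shift of 0.47, and only the mean of that list, 0.58, lay above it.

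**Figure D3:**
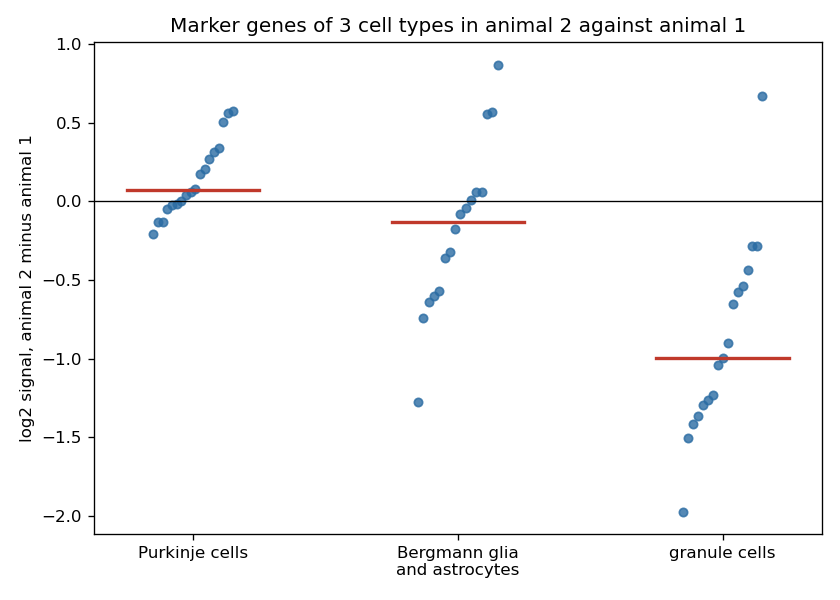
Log2 signal in animal 2 minus animal 1 (vertical axis) for each marker gene above the bound on at least 2 arrays; each point is 1 gene, the mean of 2 samples per animal, and red lines are medians. The Purkinje cell median lies at 0.07 and the glia median at -0.13, while 16 of 17 granule cell genes lie below 0, with a median of -1.0.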

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

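Among 185 measures tested for a sample far from the other 3, 10 stood out, where chance gives about 1 in 20. The tests on hybridization controls, on the granule list against the glia list, on both glia explanations, on other probe sets of called genes and on 5' to 3' ratios were chosen only after the result was seen.

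The 5' to 3' signal ratio of Actb was 0.101 in sample 2-1 against 0.0283 to 0.0407 in the others. The median percentile of the metabotropic glutamate receptor signalling list was 89.95 in sample 1-1 against 91.4 to 91.5. Ugt8a, an enzyme of myelin lipid synthesis, was at 6.73 in sample 2-2 against 8.57 to 8.84, and Hsd11b1 at 6.5 in sample 2-2 against 8.06 to 8.20. Dnajb1 was at 10.46 in sample 2-1 against 11.08 to 11.11, and Gabbr1 at 11.73 in sample 2-1 against 11.58 to 11.61. Rps7 was at 11.85 in sample 2-2 against 11.61 to 11.63. Fosb, below the background bound on every array, was at 2.44 in sample 1-1 against -0.05 to 0.22. Itm2b was at 13.23 in sample 1-1 against 13.20, and Stmn3 at 13.64 in sample 2-2 against 13.60 on each of the others, where quantile normalization gave equal ranks equal values.

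Hybridization controls, which the comparisons do not use, had a median ratio of animal 2 to animal 1 of 1.93 (range 1.57 to 2.43 over 9 probe sets), while samples of 1 animal differed by at most 1.17 on any of them. Poly-A controls, added to the RNA, did not all follow this: ratios were 1.48 to 4.10 over dap and thr, and 0.738 to 1.02 over phe and lys, where samples of 1 animal differed by up to 2.69. The trimmed mean signal differed by a ratio of 1.42.

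Granule cell genes were lower in animal 2, by a median of -1.0 over 17 genes, or -0.47 on values as deposited, a call lost with an estimated correlation (adjusted p = 0.471 against 0.00157; 5 of the 21 measured genes of the list are also on another list). A lower share of every cell type other than Purkinje cells stays open. The granule median lay below the glia median (difference -0.87, permutation p = 4.60e-04 over genes). In pairs of samples from different animals the difference was -1.15, -0.77 and -0.50, but -0.33 in 1 such pair, where samples of 1 animal differed by up to 0.40. In addition, 8 of 16 glia genes were lower in both samples of animal 2, against 25.1% of other genes (p = 0.0377, Fisher's exact test). Lists of interneurons, blood vessels and microglia (3 genes) also lay low among matched random lists, at the 0.51, 0.10 and 1.45 percentiles. Oligodendrocytes lay at the 6.03 and glia at the 31.2. Receptor subunits, which are not a cell type list but share 3 genes with the granule list, lay at the 0.28. None of these lists was called in the comparison reported. A shift of dim genes after normalization is argued against by the matched random lists, where the granule median fell at the 0.01 percentile, the smallest that 10000 lists can give. Different hybridization or scanning of the animals cannot be told apart from an animal difference, since the ratio of 1.93 of the hybridization controls follows the animals, though phe and lys do not, and fewer granule cells in the captures may also account for it.

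Bergmann glia and astrocyte genes lay above background in 15 of 18 cases. A bound that lets markers of any type pass would also pass those of microglia and blood vessels. Of their 30 genes, 3 passed (p = 4.62e-07 against the glia list, Fisher's exact test). These lists were picked after their counts were known, so this p tests no prediction. Oligodendrocyte genes passed in 3 of 15 cases and interneuron genes in 2 of 13, but granule cell genes in 11 of 21. Glial cells or their processes taken with the Purkinje cells cannot be told apart from expression of these genes in Purkinje cells themselves, since both would place them above background. A varying share of glia would move the list together between samples of 1 animal, and against matched random lists the smaller adjusted p of the 2 animals was 0.0504.

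Of the probe sets that differ between the animals, 20 were called in the real split and at most 0 in the other splits (1 of 3 splits gave as many calls, the real one), and 3 splits are too few for a share under 0.05. A difference of whole transcripts stays open: of 34 other probe sets of the same genes that normalization did not fix, 27 had the sign of the called one and 7 the other sign. Their sizes were not tested against it, because the called probe set of each gene was picked for its size. Among the 27 were 1438403_s_at of Malat1, 1433888_at of Atp2b2 and 1439036_a_at of Atp1b1, which were called themselves and so were picked by the same test. A difference in RNA integrity or amplification length could favour some probe sets over others, and for the called probe sets it cannot be told apart from an animal difference. Of 6 control transcripts, 4 had a higher 5' to 3' ratio in both samples of animal 2, and phe and lys did not. Among the 4, dap and thr were added to the RNA, so their shift is not a difference of the animals' own transcripts. All ratios were low, from 0.023 (dap, sample 1-1) to 0.16 (Gapdh, sample 2-1). Whether this dimmed probe sets far from the 3' end was not tested.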

How the results depend on the processing

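The leave-one-out values of the spread were chosen after seeing the data. The number of genes above background was 4193 with the bound at the 99th percentile, against 6502, and lay from 6586 to 7039 with single samples left out; every other alternative kept it within 1.5 times, and the number of lists called above other genes stayed between 8 and 10 in all of them. The count of probe sets that differed between animals, 20, was 243 on values as deposited, 106 with the bound passed on all 4 arrays, 46 with an offset of 16, 5 with no filter (45037 probe sets tested), 0 without trend (1883 at an unadjusted p under 0.05) and 2 to 1241 with single samples left out; 20 were called with cyclic loess, of which 19 were also called in the comparison reported. With single samples left out, the lone sample of an animal is assumed to vary like the others. The share of calls higher in animal 2 was 70% in the comparison reported, 99.2% as deposited, 58.7% with the offset, 54.7% with all 4 arrays and 30.9% to 100% with single samples left out; no called probe set that was tested again reversed its direction. With the sample number as a replicate block 187 probe sets were called (52.4% higher), including the same 20; same-numbered samples did not deviate together (correlation -0.012), so the numbers do not pair them. The granule call was lost with an estimated correlation (0 lists called) and kept as deposited, with the offset, with the replicate block and with each sample left out, with adjusted p from 1.41e-04 to 0.0242 and medians from -1.11 to -0.47; with single samples left out 1 list was called each time, and as deposited 8. The spread difference of 0.12 was 0.26 as deposited, 0.10 over all probe sets, 0.11 with the offset and 0.035 to 0.20 with single samples left out. Shares of uncalled lists crossed the share of other genes for immediate early genes (22.2%) and nuclear receptors (29.0%) at the 99th percentile, nuclear receptors without probe sets that can bind several transcripts (35.5%) or without single samples (38.7%), sex chromosome genes with the median over probe sets (25.0%) and interneuron genes with the bound at the 90th percentile or passed on at least 2 arrays (61.5%). Causes were not tested, except that fewer samples or probe sets were used where the setting says so. Levels of named genes moved by over 1 SD of the 2 animals in 119 cases and by less in 312. Signal over background limits genes near the bound.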

Other observations

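The levels and the background bound of this part were planned, and Thra, Star, Atp2b2 and Atp2b4 were named by the rule set beforehand. The other genes were chosen only after their values were seen. Genes of nuclear hormone receptors that were not named above also passed the background bound on all 4 arrays in these samples, where glial markers passed too. Among these receptor genes were the thyroid hormone receptor gene Thra at 8.28 ± 0.17 (SD, n = 2 animals) and the glucocorticoid receptor gene Nr3c1 at 7.82 ± 0.22. The mineralocorticoid receptor gene Nr3c2 was at 6.96 ± 0.22 and Nr4a3 at 7.25 ± 0.38. Which of the captured cells gave these signals was not tested. The estrogen receptor genes Esr1 and Esr2 lay below the bound on every array, at 1.43 ± 1.83 and 0.78 ± 0.66, where values carry little information. Of the steroid synthesis genes, Star passed the bound on 1 array, and Cyp11a1, which starts the pathway from cholesterol, on none (2.82 ± 0.26).

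Among calcium pumps, Atp2b2 (11.23 ± 0.68), Atp2b1 (7.18 ± 0.44) and Atp2b3 (7.19 ± 0.49) lay above the bound on all 4 arrays, and Atp2b4 (1.92 ± 0.52) on none. Of the ryanodine receptor genes, Ryr1 was at 6.78 ± 0.51 and Ryr2 at 6.42 ± 0.41. Each value belongs to 1 probe set.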
